A study of Mus musculus with 6 samples.

How the data were processed

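Total RNA of femur macrophages sorted as CD11b+F4/80+ cells was extracted with a Qiagen kit, and libraries were made with standard Illumina protocols, per the labels' protocols. The 6 libraries formed 3 groups of 2 by their labels: mice without a graft (day 0), and mice 4 days (day 4) or 18 days (day 18) after they received Raji cells. Reads were aligned to the mouse genome build mm10 with STAR 2.5.3a, per the submitters' processing notes. The counting tool, the gene annotation and the filter on genes are not given in the sources used here.

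The deposited table lists a symbol, a position and 1 value per library for 17528 genes. Its name calls the values raw counts, but the values are RPKM, as the deposited values themselves show: multiplied by the length of the whole gene in kilobases, introns included, each library sums to 1000000. The steps between low values then give the worth of 1 read, and so the number of reads assigned to listed genes: 23214522 (day 0 A), 22363762 (day 0 B), 21815203 (day 4 A), 20383223 (day 4 B), 20073017 (day 18 A) and 22600763 (day 18 B). The letters are those of the deposited columns, which the labels do not use. Every listed gene had at least 10 reads in total. In each library 74.8% to 76.0% of genes had a whole number of reads, as did 80.3% to 81.6% of genes under 100 reads. The others held fractions, as when reads that match several genes are divided among them. For these shares whole reads were taken within 0.05 reads. Elsewhere 1e-05 per read was added, and 66 tested genes above a mean of 20000 reads could not be judged. The alternative with whole reads only kept these 66 genes. These tolerances were set after the values were seen. Symbols were matched to the GENCODE M21 annotation of the same build for gene type: 17089 were found, 16922 with the same span, and 12986 listed genes were protein-coding and 1433 processed pseudogenes.

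Groups, comparisons, gene lists, the threshold, the rule for naming genes and most alternatives were fixed before the data were examined. The count-model test planned then was replaced by limma, which takes values that are not counts, because the deposited values are RPKM. The use of reads per 1000000 (RPM), the pseudocount of 0.1 and the 8 tests of explanations in the closing section were chosen after the data were seen, as were the alternatives with other pseudocounts, RPKM scale, other trends of the spread, whole reads only, without the 20 most abundant genes and with the letter of the column as a block.

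Values were turned into RPM. Scaling factors were computed by trimmed mean of M values (trimming 0.3 of M and 0.05 of A values on each side), and were 0.970, 0.967, 1.01, 1.00, 1.03 and 1.03 in the order of libraries above. Genes were tested if at least 2 libraries held 10 reads at the median library size (0.453 RPM) and all libraries together at least 15, which left 14304. Log2 of RPM plus 0.1 was compared with limma 3.58.1 in R 4.3.3, with 1 model of all 6 libraries, a spread that follows the level, and robust moderation (3 residual and a median of 22.9 prior degrees of freedom). Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05. Fold changes on this scale understate those of genes with few reads. The 42 fixed gene lists (20 of pathways, 17 of cell markers and 5 of technical signs), all with at least 5 tested genes, were compared with the other genes by camera with a preset correlation of 0.01, and by camera with the correlation estimated from the data and by fry as alternatives, adjusted over the 42 lists. With an estimated correlation camera also tests each list on the residual degrees of freedom, 3 here. A call lost with that setting thus does not by itself show correlated members. Some lists share members, so their calls are not independent. Member counts were also adjusted over the list alone. The similarity of the changes at day 4 and day 18 was compared with 100 simulated draws of unchanged groups. All 6 libraries were simulated, with both changes measured against the same simulated day 0 libraries. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

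Named genes followed a rule. In each comparison these were the 8 largest rises and 8 largest falls among called genes with a mean log2 level of at least 3, libraries of the groups that do not overlap and a symbol other than a model name. For each list called by camera, and the 4 lists with the highest share of called members, they were the 3 members with the smallest p in the main direction with a mean log2 level of at least 1. In every comparison the genes Itgam, Adgre1, Csf1r, Cd68, Ptprc, Sirpa, Fcgr1, Fcgr2b, Fcgr3, Fcgr4, Cd274, Vegfa, Arg1, Mrc1, Il1b and Tnf were reported whatever the result. A few genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen. The test was tried on simulated libraries with 14101 genes and 200 changed genes per comparison. All simulated genes had the same spread beyond counting noise. For day 4 against day 0 it recovered 58.3% of changes of 1.25-fold, 70.0% of 1.5-fold, 89.8% of 2-fold and 98.0% of 4-fold, with 6.06% of calls false. For day 18 against day 0, camera called 5 of 5 changed lists and 0 of 200 unchanged lists. The simulated genes varied independently, and the changed lists held only genes raised at least 1.5-fold. This cannot measure false calls of lists with correlated members, such as the mitochondrially encoded genes (estimated correlation 0.338). Alternatives covered limma-voom, other scaling factors, filters, pseudocounts, moderation, sets of libraries and list tests, and leaving out each library.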

Results

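RNA was sequenced from bone marrow macrophages sorted from mouse femurs as CD11b+F4/80+ cells. The mice were BALB/c animals lacking Rag2 and the common cytokine receptor gamma chain (RAG2-/-γc-/-), a background without mature T, B and NK cells that accepts human grafts. Cells came from mice without a graft (day 0) and from mice 4 and 18 days after intravenous engraftment of Raji cells, a human Burkitt lymphoma line used as a model of non-Hodgkin lymphoma. Each of the 3 groups had 2 libraries, called A and B here, which gives 6 libraries in all. No group of ungrafted mice matches the later days, so the graft, the injection and the time passed cannot be told apart. Reads assigned to genes numbered 23214522 and 22363762 at day 0, 21815203 and 20383223 at day 4, and 20073017 and 22600763 at day 18. Of 17528 listed genes, 14304 were tested. The labels list the 2 libraries of a group as separate samples, and they were counted so. They differed by more than sampling noise, with a chi-square per gene of 3.42 at day 0, 4.78 at day 4 and 2.48 at day 18, as technical replicates can also do. The labels do not say whether the libraries of a group came from separate animals, so the p-values below measure only the spread between these libraries, which may be technical. At this depth the median standard error of a log2 fold change was 0.11. Levels below are RPM (assigned reads per 1000000, after scaling), as mean ± SD of the 2 libraries of a group (n = 2 throughout). Changes are log2 fold changes ± standard error, and p-values are from limma, adjusted by the Benjamini-Hochberg method over all tested genes, unless another test is named.

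The sorted cells expressed the genes behind the sorting antibodies: Itgam, which encodes CD11b, stood at 2311 ± 17.5 at day 0 and Adgre1, which encodes F4/80, at 34.6 ± 0.966. The macrophage growth factor receptor gene Csf1r stood at 159.5 ± 5.03 and Cd68, a lysosomal membrane protein of macrophages, at 36.6 ± 2.78. The most abundant transcripts were those of neutrophil granules and cytosol: Ngp held 3.40% of all reads on average, S100a9 3.21%, S100a8 1.98% and Ltf 1.94%. The 20 genes of the late neutrophil list together took 14.6 ± 0.00762% of reads at day 0, 13.2 ± 0.267% at day 4 and 11.6 ± 0.0586% at day 18 (n = 2). The genes named in the genotype, looked up after the values were seen, had reads in every library: Rag2 had 39 and 47 reads at day 0, 48 and 45 at day 4, and 105 and 90 at day 18, and Il2rg stood at 31.7 ± 2.88 at day 0. All mice had the same genotype, so this checks no group label. These reads do not by themselves bear out the loss of either gene. Totals per gene do not show where in a gene the reads lie, so a deleted part could not be examined.

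The comparison of day 4 with day 0 asks what changed soon after engraftment. Genes of patrolling monocytes and of neutrophil primary granules were higher at day 4, while genes of resident macrophages, haemoglobin chains and some inflammatory mediators were lower. Camera called these 5 lists with its preset correlation only: with an estimated correlation, in the order named, adjusted p = 0.0857, 0.0821, 0.0857, 0.0857 and 0.134. Ace, angiotensin-converting enzyme and a marker of non-classical monocytes, rose from 37.7 ± 0.494 to 81.7 ± 0.806 (2.17-fold). Mpo, the myeloperoxidase of primary granules, rose from 1198 ± 3.14 to 1987 ± 5.05 (1.66-fold). Cd5l, a secreted scavenger receptor protein of macrophages, fell from 22.99 ± 1.65 to 11.9 ± 0.715, and Cxcl2, a chemokine that attracts neutrophils, fell from 40.7 ± 1.87 to 22.8 ± 0.476. Most changes were small: the median absolute log2 fold change of the called genes was 0.24, and 91 of the 1736 called genes changed at least 2-fold.

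Among genes with a mean log2 level of at least 3 and no overlap between the groups, the largest rises at day 4 were those of S1pr5, a sphingosine phosphate receptor (1.12 ± 0.170), Ace (1.11 ± 0.0581, adjusted p = 1.15e-13), Ms4a4a, a membrane protein of macrophages (1.03 ± 0.135), the transcription factor gene Pou2f2 (1.03 ± 0.0821), Cd244a (0.97), Arl5c (0.95), Lat2 (0.94) and Cd274 (0.94 ± 0.134). Cd274 encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095 in mm10, plus strand, a protein-coding gene), and rose from 4.96 ± 0.240 to 9.58 ± 0.341. Ace lies on chromosome 11, 105967945 to 105989964, on the plus strand. The largest falls among such genes were those of Hcar2, a receptor for hydroxycarboxylic acids (-1.07 ± 0.108, adjusted p = 4.79e-08), Acot1 (-0.96), Cd5l (-0.95), the haemoglobin genes Hbb-bs (-0.94) and Hba-a2 (-0.93), the lipoxygenase gene Alox15 (-0.90 ± 0.0678), Zfp979 (-0.87) and the eosinophil-associated ribonuclease gene Ear1 (-0.86). Reads of Lat2, Cd274, Acot1, Hbb-bs, Hba-a2, Zfp979 and Ear1 were not whole numbers, as when reads are divided among overlapping or near-identical genes, so these values are uncertain to that extent. The same holds below for Csf1r, Ptprc, Sirpa, Fcgr2b, Fcgr3, Apoe, Prtn3, Myb, Plac8, Slfn5, Hspa5, Ctss, Pirb, Lilrb4a, Top2a, Cxcl16, Dusp1 and Lgals3.

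In the non-classical monocyte list at day 4, 8 of 12 rose and 0 fell (9 and 1 adjusted over the list alone), with Cd300e at 1.26 ± 0.169 and the chemokine receptor gene Cx3cr1 at 0.55 ± 0.0543 (camera adjusted p = 2.96e-07, and adjusted p = 0.0857 with an estimated correlation). In the classical monocyte list, 6 of 17 rose and 6 fell (7 and 8 adjusted over the list alone). Its chemokine receptor gene Ccr2 rose (0.53 ± 0.0309), as did Plac8 (0.39) and F13a1 (0.43), and camera did not call the list (adjusted p = 0.888). Of the early neutrophil markers, 9 of 12 rose and 2 fell (10 and 2 adjusted over the list alone), with Elane, neutrophil elastase, at 0.67 ± 0.0233 and Prtn3, proteinase 3, at 0.68 (camera adjusted p = 1.97e-13, and adjusted p = 0.0821 with an estimated correlation). Of the late neutrophil markers, 0 of 20 rose and 14 fell (0 and 15 adjusted over the list alone), including Ltf (-0.20), Ngp (-0.21) and Mmp8 (-0.51), with camera adjusted p = 5.95e-24, and adjusted p = 0.0660 with an estimated correlation. Basophil and mast cell proteases were low but higher at day 4: Prss34 rose from 6.21 ± 0.177 to 17.9 ± 0.835 and Mcpt8 from 4.27 ± 0.871 to 10.6 ± 0.514. In that list 4 of 9 rose and 0 fell (5 and 0 adjusted over the list alone), with camera adjusted p = 0.000180, and adjusted p = 0.138 with an estimated correlation. The haematopoietic progenitor list had 3 risers of 11, among them the transcription factor gene Myb (0.25 ± 0.0408), and 0 fallers (3 and 0 adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 0.370 with an estimated correlation).

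Resident macrophage genes were mostly lower at day 4. In that list, 2 of 19 rose and 10 fell (2 and 13 adjusted over the list alone), with the haem oxygenase gene Hmox1 at -0.51 ± 0.0483, Axl, a receptor for apoptotic cells, at -0.41 ± 0.0576 and Cd5l at -0.95 ± 0.105 (camera adjusted p = 6.33e-08, and adjusted p = 0.0857 with an estimated correlation). Complement genes fell in part: 2 of 8 rose and 5 fell (2 and 5 adjusted over the list alone), with the C1q subunit genes C1qa at -0.51 and C1qb at -0.62 and C3 at -0.17 (camera adjusted p = 0.00786, and adjusted p = 0.168 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets had 0 risers and 12 fallers of 34 (1 and 12 adjusted over the list alone), the fallers including Cxcl2 (-0.83 ± 0.0640), Ccrl2 (-0.68) and Ptgs2, inducible cyclooxygenase (-0.83), with camera adjusted p = 0.000262, and adjusted p = 0.134 with an estimated correlation. Erythroid genes fell in part: 0 of 14 rose and 6 fell (0 and 7 adjusted over the list alone), with Hba-a1 at -0.75 (camera adjusted p = 3.48e-07, and adjusted p = 0.0857 with an estimated correlation). The reads of Hba-a1 were not whole numbers and may be shared with its copy Hba-a2. Eosinophil-list genes also fell in part: 1 of 11 rose and 6 fell (1 and 6 adjusted over the list alone), with Ear6 at -0.71 (camera adjusted p = 0.000262, and adjusted p = 0.168 with an estimated correlation). Outside the naming rule and looked up after the values were seen, the eosinophil peroxidase gene Epx rose (0.55, adjusted p = 8.37e-06), against the direction of its list. In the osteoclast list 0 of 8 rose and 3 fell (0 and 4 adjusted over the list alone), and in the stromal and osteoblast list 0 of 8 rose and 2 fell (0 and 3 adjusted over the list alone), where Cxcl12, the chemokine of marrow stroma, fell from 9.65 ± 0.148 to 4.34 ± 0.227. Adjusted p were 0.00147 and 0.0129 by camera, and adjusted p = 0.168 and 0.191 with an estimated correlation.

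In the type I interferon list at day 4, 12 of 45 rose and 2 fell (13 and 2 adjusted over the list alone), with Slfn5 at 0.52 ± 0.0546 and Ifi44 at 0.54 ± 0.0858 (camera adjusted p = 0.000137, and adjusted p = 0.168 with an estimated correlation). In the interferon gamma list, 4 of 21 rose and 0 fell (5 and 1 adjusted over the list alone), with the transcription factor gene Irf8 at 0.50 ± 0.0673 (camera adjusted p = 0.0121, and adjusted p = 0.168 with an estimated correlation). Of the lipid genes, 8 of 26 rose and 3 fell (9 and 4 adjusted over the list alone), with the lipoprotein genes Apoe at 0.65 ± 0.0253 and Apoc2 at 1.16 ± 0.178 (camera adjusted p = 0.0397, and adjusted p = 0.191 with an estimated correlation). Of the ribosomal protein genes, 18 of 44 rose and 1 fell (24 and 1 adjusted over the list alone), and these have many near-identical copies (camera adjusted p = 1.61e-15, and adjusted p = 0.171 with an estimated correlation). Small falls were seen in 4 further lists. In the cell cycle list 5 of 51 rose and 9 fell (5 and 10 adjusted over the list alone), with the proliferation marker Mki67 at -0.23. In the endoplasmic reticulum stress list 1 of 24 rose and 5 fell (1 and 5 adjusted over the list alone), with the chaperone gene Hspa5 at -0.21. In the angiogenesis and matrix list 2 of 25 rose and 6 fell (2 and 8 adjusted over the list alone), with Thbs1, thrombospondin 1, at -0.63. In the Fc and complement receptor list 3 of 24 rose and 5 fell (4 and 7 adjusted over the list alone), with the integrin gene Itgb2 at -0.12. For these 4, in that order, camera gave adjusted p of 0.0179, 0.00786, 0.0202 and 0.0468, and adjusted p = 0.255, 0.168, 0.185 and 0.428 with an estimated correlation. Of the genes reported whatever the result, Csf1r (0.39 ± 0.0349), Cd68 (0.34) and Adgre1 (0.33) rose, and Itgam (-0.18), Ptprc (-0.11), Mrc1 (-0.42) and Il1b (-0.31) fell. Values for Sirpa (0.03 ± 0.0225), Fcgr3 (-0.03 ± 0.0338), Fcgr4 (0.17 ± 0.0696), Vegfa (0.05 ± 0.0480), Arg1 (-0.85 ± 0.639) and Tnf (0.10 ± 0.0555) did not pass the test. The Fc receptor genes Fcgr1 (0.48 ± 0.128, adjusted p = 0.0134) and Fcgr2b (0.15 ± 0.0380, adjusted p = 0.00676) passed. Fcgr1 no longer did without day 0 A (adjusted p = 0.319), day 4 A (0.0538) or day 4 B (0.0650), nor Fcgr2b without day 0 B (0.0847) or day 4 A (0.0892). Ptprc did not pass with library totals alone (adjusted p = 0.125), nor Fcgr1 with only the 4 libraries compared (0.0562).

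By limma, 1736 genes changed between day 0 and day 4, 784 higher and 952 lower (3473 genes at an unadjusted p under 0.05), and camera called 20 of the 42 lists, 8 up and 12 down. With an estimated correlation camera called 0 lists, against 25 by fry, which does not compare a list with other genes. With library totals alone in place of the scaling factors, with which the median of all genes was 0.0574 instead of 0.00473, 1722 genes were called, 1261 higher and 461 lower, so the share of risers went from 45.2% to 73.2%. Only 12 genes, 6 higher and 6 lower, differed by more than 1.5-fold by limma's test against that fold, and the count was 998 without day 0 A and 916 without day 0 B. This count rests on the model of the spread: on the RPKM scale limma called 95 genes (65 higher, 30 lower) with a pseudocount of 0.1, 52 (37 higher, 15 lower) with 1. With the spread following RPM it called 748 (343 higher, 405 lower), and with 1 spread for all levels 0. Calls of 7 lists ended when 1 library was left out. They were the interferon gamma list without day 4 A (adjusted p = 0.0554), the Fc receptor list without day 0 A (0.0521), day 0 B (0.125) or day 4 B (0.206), the cell cycle list without day 4 B (0.0880), the lipid list without day 0 A (0.0630) or day 4 B (0.0709), the angiogenesis list without day 0 A (0.0630), the stromal list without day 4 B (0.0630) and the progenitor list without day 4 A (0.180). Without the 20 most abundant genes the complement list was not called (0.0700). With whole reads only, the calls of cell cycle (0.104), lipid (0.177), endoplasmic reticulum stress (0.240), erythroid (0.0673) and progenitor (0.0673) genes ended.

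The comparison of day 18 with day 0 asks what differed 18 days after engraftment. Inflammatory, antigen presentation, interferon, lysosomal and immediate early genes were higher at day 18, and cell cycle and late neutrophil genes were lower. Of these lists only the inflammatory, lysosomal and cell cycle ones kept their call with an estimated correlation: the others had adjusted p = 0.0764 (MHC class II), 0.111 (class I), 0.0764 and 0.0704 (interferon), 0.0680 (immediate early) and 0.0680 (late neutrophil). Socs3, a feedback inhibitor of cytokine signalling (chromosome 11, 117966079 to 117970047 in mm10, minus strand, protein-coding), rose from 13.7 ± 1.90 to 179 ± 5.78 (13.04-fold). Cxcl2 rose from 40.7 ± 1.87 to 163 ± 2.83 (4.00-fold), and the interleukin 1 beta gene Il1b from 78.5 ± 3.52 to 188 ± 1.83 (2.40-fold). The MHC class II gene H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand, protein-coding) rose from 145 ± 5.91 to 392 ± 1.75 (2.70-fold). Mki67 fell from 1257 ± 13.5 to 810.0 ± 0.318 (-0.63 ± 0.0194). Rises were larger than falls: of 811 called genes that changed at least 2-fold, 771 were higher and 40 lower.

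The largest rises among genes with a mean log2 level of at least 3 were those of Cfb, complement factor B (4.24 ± 0.149, adjusted p = 2.24e-18, chromosome 17, 34856374 to 34862518, minus strand), Socs3 (3.71 ± 0.0930), the transglutaminase gene Tgm2 (3.38 ± 0.126), Ms4a4a (3.19), Ms4a6d (2.98), Bcl3, an atypical IkB protein (2.85), Msr1, a class A scavenger receptor (2.70) and Tgfbi, a matrix protein induced by transforming growth factor beta (2.51 ± 0.0379). Tgfbi went from 109 ± 4.06 to 622 ± 5.92. The reads of Cfb, Ms4a6d and Tgfbi were not whole numbers, so part of them may belong to overlapping or similar genes. The largest falls among such genes were smaller: Cd209a, a C-type lectin (-1.16 ± 0.169), Fcna, a ficolin of resident macrophages (-0.96 ± 0.114), the cohesin gene Stag3 (-0.89), the lysozyme gene Lyz1 (-0.86), Nanos1 (-0.85), Klhl42 (-0.85), Neto2 (-0.81) and the zinc transporter gene Slc39a11 (-0.81).

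**Figure D1:**
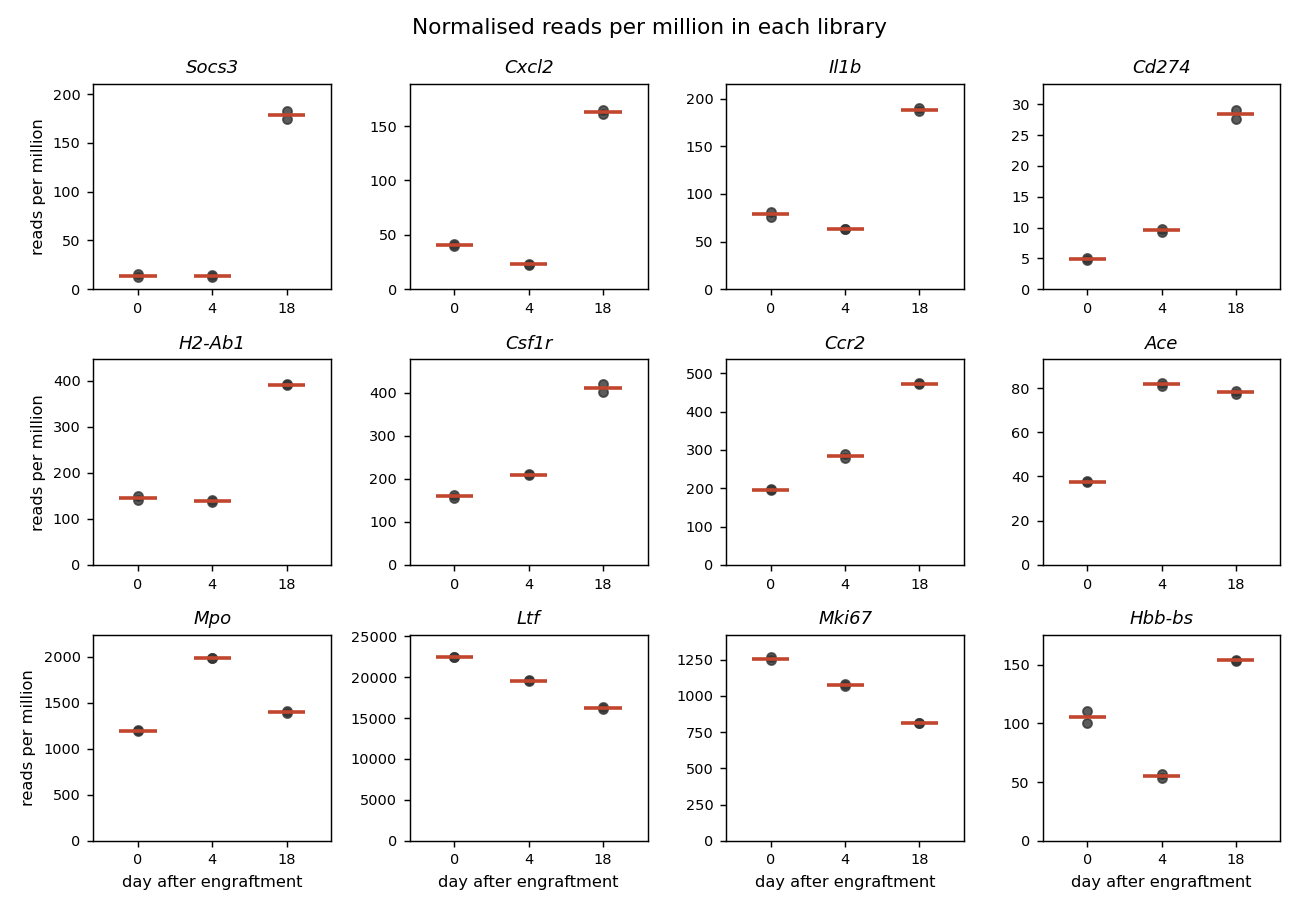
RPM after scaling (vertical axis, from 0) of 12 genes at day 0, 4 and 18 after engraftment (horizontal axis), with 1 point per library and a bar at the mean of the 2 libraries of a group. Socs3 went from 13.7 at day 0 to 179 at day 18, while Mki67 fell from 1257 to 810.0, and the libraries of a group lie close together beside these differences.

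Inflammatory genes rose almost without exception at day 18. In the list of inflammatory cytokines and NF-kB targets, 32 of 34 rose and 0 fell (32 and 0 adjusted over the list alone), with Cxcl2 at 2.00 ± 0.0640 and Nfkbia, the IkB alpha gene, at 0.98 ± 0.0343, and a list median of 1.42. It was 1 of 3 lists that camera called with either correlation (adjusted p = 5.40e-20, and adjusted p = 0.0492 with an estimated correlation). Saa3, an acute phase protein of this list singled out after its values were seen, had 0 and 1 reads at day 0, 0 and 1 at day 4, and 4007 and 4330 at day 18. Its day 18 level was 8904 times that of day 0, with a 95% interval from 1598 to 351700 that covers counting error alone, not the spread between libraries, and rests on 1 read at day 0. Immediate early genes, which also respond to tissue handling, rose too: 21 of 24 rose and 1 fell (21 and 1 adjusted over the list alone), with Fosb at 1.11 ± 0.0328, Dusp1 at 0.83 and Fos at 0.68 (camera adjusted p = 1.41e-15, and adjusted p = 0.0680 with an estimated correlation). In the heat shock list 6 of 12 rose and 2 fell (7 and 2 adjusted over the list alone), and camera did not call it (adjusted p = 0.0869). Complement genes rose: 7 of 8 rose and 1 fell (7 and 1 adjusted over the list alone), with Cfp, properdin, at 0.48 ± 0.0461 (camera adjusted p = 0.000112, and adjusted p = 0.0876 with an estimated correlation).

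Antigen presentation and interferon genes rose at day 18. Of the MHC class II genes, 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), with the invariant chain gene Cd74 at 1.22 ± 0.0259, H2-Ab1 at 1.43 and the cathepsin S gene Ctss at 1.73 ± 0.0395 (camera adjusted p = 1.40e-11, and adjusted p = 0.0764 with an estimated correlation). Of the MHC class I genes, 11 of 18 rose and 0 fell (12 and 0 adjusted over the list alone), with H2-K1 at 0.63, H2-D1 at 0.32 and H2-Q7 at 2.64 (camera adjusted p = 1.57e-05, and adjusted p = 0.111 with an estimated correlation). The reads of all 3 genes were not whole numbers and may be shared among similar class I genes. In the type I interferon list, 30 of 45 rose and 4 fell (32 and 4 adjusted over the list alone), with Ms4a4c at 1.56 ± 0.0792 and Slfn5 at 1.11 ± 0.0546 (camera adjusted p = 1.13e-09, and adjusted p = 0.0764 with an estimated correlation). In the interferon gamma list, 15 of 21 rose and 0 fell (16 and 0 adjusted over the list alone), with Irf8 at 1.09 and the chemokine gene Cxcl10, which rose from 5.01 ± 0.303 to 17.7 ± 0.204 (camera adjusted p = 4.90e-07, and adjusted p = 0.0704 with an estimated correlation). Among immune inhibitory genes, 11 of 21 rose and 5 fell (11 and 6 adjusted over the list alone). Cd274 rose from 4.96 ± 0.240 to 28.3 ± 1.05 (2.49 ± 0.134), Pirb by 0.56 and Lilrb4a by 0.48 (camera adjusted p = 0.00252, and adjusted p = 0.140 with an estimated correlation). In the list of lymphocyte survival and homing factors, 8 of 13 rose and 3 fell (8 and 3 adjusted over the list alone), with the adhesion gene Icam1 at 2.47 ± 0.0946, the chemokine gene Cxcl16 at 3.61 ± 0.198 and the costimulatory receptor gene Cd40 at 2.89 ± 0.224 (camera adjusted p = 0.0353, and adjusted p = 0.178 with an estimated correlation).

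Macrophage function lists rose in part. Of the lysosomal genes, 29 of 46 rose and 1 fell (29 and 2 adjusted over the list alone), with Ctsc, cathepsin C, at 2.27 ± 0.0510 and Psap at 0.69 ± 0.0182, and camera called the list with either correlation (adjusted p = 1.89e-11, and adjusted p = 0.0492 with an estimated correlation). Of the lipid genes 17 of 26 rose and 2 fell (17 and 2 adjusted over the list alone), including Nr1h3, the liver X receptor alpha gene (2.12 ± 0.186), and Apoe (0.98). Of the scavenger receptor genes 10 of 25 rose and 6 fell (10 and 6 adjusted over the list alone), including Lrp1 (1.24) and Cd14, a coreceptor for lipopolysaccharide (1.62). Of the haem and iron genes 13 of 23 rose and 4 fell (13 and 4 adjusted over the list alone), including the ferritin gene Fth1 (0.71). For these 3 lists, in that order, camera gave adjusted p of 6.07e-05, 0.00744 and 0.00110, and adjusted p = 0.0801, 0.111 and 0.0911 with an estimated correlation. In the alternative activation list 13 of 23 rose and 5 fell (14 and 5 adjusted over the list alone). Fn1, fibronectin, rose (1.35 ± 0.0286), as did Arg1 from 0.180 ± 0.0589 to 2.596 ± 0.109, while the mannose receptor gene Mrc1 fell (-0.44 ± 0.0700), with camera adjusted p = 0.000699, and adjusted p = 0.0889 with an estimated correlation. In the angiogenesis and matrix list 11 of 25 rose and 4 fell (11 and 4 adjusted over the list alone), with the metalloproteinase gene Mmp14 rising from 2.72 ± 0.206 to 62.2 ± 0.0623 and Vegfa falling (-0.32 ± 0.0480), with camera adjusted p = 0.00744, and adjusted p = 0.112 with an estimated correlation. In the Fc and complement receptor list 14 of 24 rose and 5 fell (15 and 5 adjusted over the list alone), with Fcgr1 at 1.81 ± 0.128, Fcgr2b at 0.51, Fcgr4 at 0.61 and the integrin gene Itgax at 1.90 (camera adjusted p = 0.0190, and adjusted p = 0.318 with an estimated correlation). Fcgr3 rose by 0.12 (adjusted p = 0.00692, 0.103 without day 0 B). The macrophage genes Csf1r (1.36 ± 0.0349), Cd68 (1.08) and Adgre1 (0.83) rose, as did Sirpa (0.32) and Ptprc (0.13), and Itgam fell (-0.26). Tnf passed narrowly (0.14 ± 0.0555, adjusted p = 0.0483) and did not pass without day 0 A (adjusted p = 0.0813), day 0 B (0.261), day 18 A (0.294) or day 18 B (0.0623), with median-of-ratios factors (0.0665), without the filter on low counts (0.0586) or without the 20 most abundant genes (0.0602).

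Proliferation genes fell at day 18. In the cell cycle list 0 of 51 rose and 43 fell (0 and 46 adjusted over the list alone), with the DNA topoisomerase gene Top2a at -0.48 ± 0.0242 and the kinesin gene Cenpe at -0.68 (camera adjusted p = 2.73e-23, and adjusted p = 0.0492 with an estimated correlation). In the cholesterol synthesis list 0 of 24 rose and 10 fell (0 and 10 adjusted over the list alone), with camera adjusted p = 0.00861, and adjusted p = 0.112 with an estimated correlation. Ribosomal protein genes rose: 37 of 44 rose and 0 fell (37 and 0 adjusted over the list alone), with Rps9 at 0.60 and Rps19 at 0.72, both with reads that may be shared (camera adjusted p = 4.80e-20, and adjusted p = 0.111 with an estimated correlation). Nuclear oxidative phosphorylation genes rose slightly, 18 of 69 against 1 lower (13 and 1 adjusted over the list alone), with Cox4i1 at 0.22. Of the mitochondrially encoded genes 9 of 15 rose and 2 fell (10 and 2 adjusted over the list alone), with mt-Nd1 at 0.21. For these last 2 lists camera gave adjusted p of 0.0179 and 0.0190, and adjusted p = 0.476 and 0.474 with an estimated correlation.

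In the classical monocyte list at day 18, 9 of 17 rose and 5 fell (9 and 5 adjusted over the list alone), with Ccr2 rising from 197 ± 3.19 to 473 ± 0.583 and F13a1 at 1.38. The monocyte surface gene Ly6c2, looked up after the values were seen, fell (-0.14, adjusted p = 4.62e-05). Its reads were not whole numbers in 2 of the 6 libraries. In the non-classical monocyte list 8 of 12 rose and 2 fell (8 and 2 adjusted over the list alone), with Nr4a1, also in the immediate early list, at 0.83 and Ace at 1.05. In the eosinophil list 8 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), with the major basic protein gene Prg2 at 0.85 ± 0.043. For these 3 lists, in that order, camera gave adjusted p of 0.000297, 0.0001001 and 5.06e-05, and adjusted p = 0.0876, 0.0876 and 0.111 with an estimated correlation. Late neutrophil markers were lower: 3 of 20 rose and 13 fell (4 and 13 adjusted over the list alone), with Ltf at -0.48 ± 0.00820, Cd177 at -0.37 and Ly6g at -0.46 (camera adjusted p = 1.47e-08, and adjusted p = 0.0680 with an estimated correlation). In the plasmacytoid dendritic cell list 4 of 8 rose and 1 fell (4 and 1 adjusted over the list alone), with Bst2 at 0.77, and Siglech, looked up after the values were seen, fell from 1.31 ± 0.539 to 0.205 ± 0.0154 (adjusted p = 0.00781). For the list, camera adjusted p = 0.0353, and adjusted p = 0.178 with an estimated correlation. Bst2 is also in the type I interferon list, and Irf8, another riser of the plasmacytoid list, is in the interferon gamma list. The call is thus not independent of the rise of the interferon lists. Lists without a call from camera had both directions or few called genes. In the resident macrophage list 11 of 19 rose and 7 fell (11 and 7 adjusted over the list alone), with Fcna at -0.96 (adjusted p = 0.156). In the early neutrophil list 6 of 12 rose and 4 fell (6 and 4 adjusted over the list alone), in the erythroid list 5 of 14 rose and 1 fell (5 and 1 adjusted over the list alone), and in the conventional dendritic cell list 3 of 13 rose and 3 fell (4 and 3 adjusted over the list alone), with adjusted p of 0.520, 0.372 and 0.134.

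Several further lists had no camera call at day 18 against day 0. For the B cell list, which holds mouse genes with conserved counterparts in the engrafted cells, 0 of 7 rose and 2 fell (0 and 2 adjusted over the list alone), with an adjusted p of 0.434. In the list of T cell, NK cell and innate lymphoid genes 3 of 6 rose and 0 fell (3 and 1 adjusted over the list alone), with an adjusted p of 0.389. For the basophil and mast cell, megakaryocyte, endothelial, stromal, osteoclast and progenitor lists, the risers were 1 of 9, 1 of 9, 2 of 6, 1 of 8, 3 of 8 and 1 of 11, and the fallers 2, 0, 1, 1, 0 and 2. Adjusted over the list alone, the risers were 1, 1, 2, 1, 3 and 1 and the fallers 2, 0, 2, 1, 0 and 2, and camera gave adjusted p of 0.260, 0.953, 0.686, 0.520, 0.479 and 0.520. In the glycolysis and hypoxia list 10 of 34 rose and 13 fell (11 and 13 adjusted over the list alone), in the endoplasmic reticulum stress list 9 of 24 rose and 4 fell (9 and 4 adjusted over the list alone), and in the histone list 1 of 21 rose and 2 fell (0 and 2 adjusted over the list alone), with adjusted p of 0.601, 0.479 and 0.773.

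By limma, 5048 genes changed between day 0 and day 18, 2578 higher and 2470 lower (6132 at an unadjusted p under 0.05), with a median absolute log2 fold change of 0.36. Camera called 26 of 42 lists, 23 up and 3 down, of which 3 held with an estimated correlation: inflammatory, lysosome and cell cycle. With library totals alone, with which the median of all genes was 0.0986 instead of 0.0152, 4855 genes were called, 3432 higher and 1423 lower, so the share of risers went from 51.1% to 70.7%, and 19 called genes had the opposite sign. Against a 1.5-fold change, limma called 505 genes higher and 12 lower. On the RPKM scale it called 3376 genes (1948 higher, 1428 lower) with a pseudocount of 0.1 and 3430 (1966 higher, 1464 lower) with 1. With 1 spread for all levels it called 2646 (1656 higher, 990 lower). List calls that ended without 1 library were those of oxidative phosphorylation without day 0 A (adjusted p = 0.0731) or day 18 B (0.0851), lymphocyte survival factors without day 0 A (0.0523), day 18 A (0.164) or day 18 B (0.196), plasmacytoid dendritic cells without day 0 B (0.0631) and mitochondrially encoded genes without day 0 B (0.0679) or day 18 B (0.0861). With whole reads only, the calls of immune inhibitory (0.249), Fc and complement receptor (0.470), cholesterol (0.0536), angiogenesis (0.0639), lymphocyte survival (0.0917) and mitochondrially encoded (0.170) genes ended, and without the filter on low counts that of plasmacytoid dendritic cells (0.149).

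**Figure D2:**
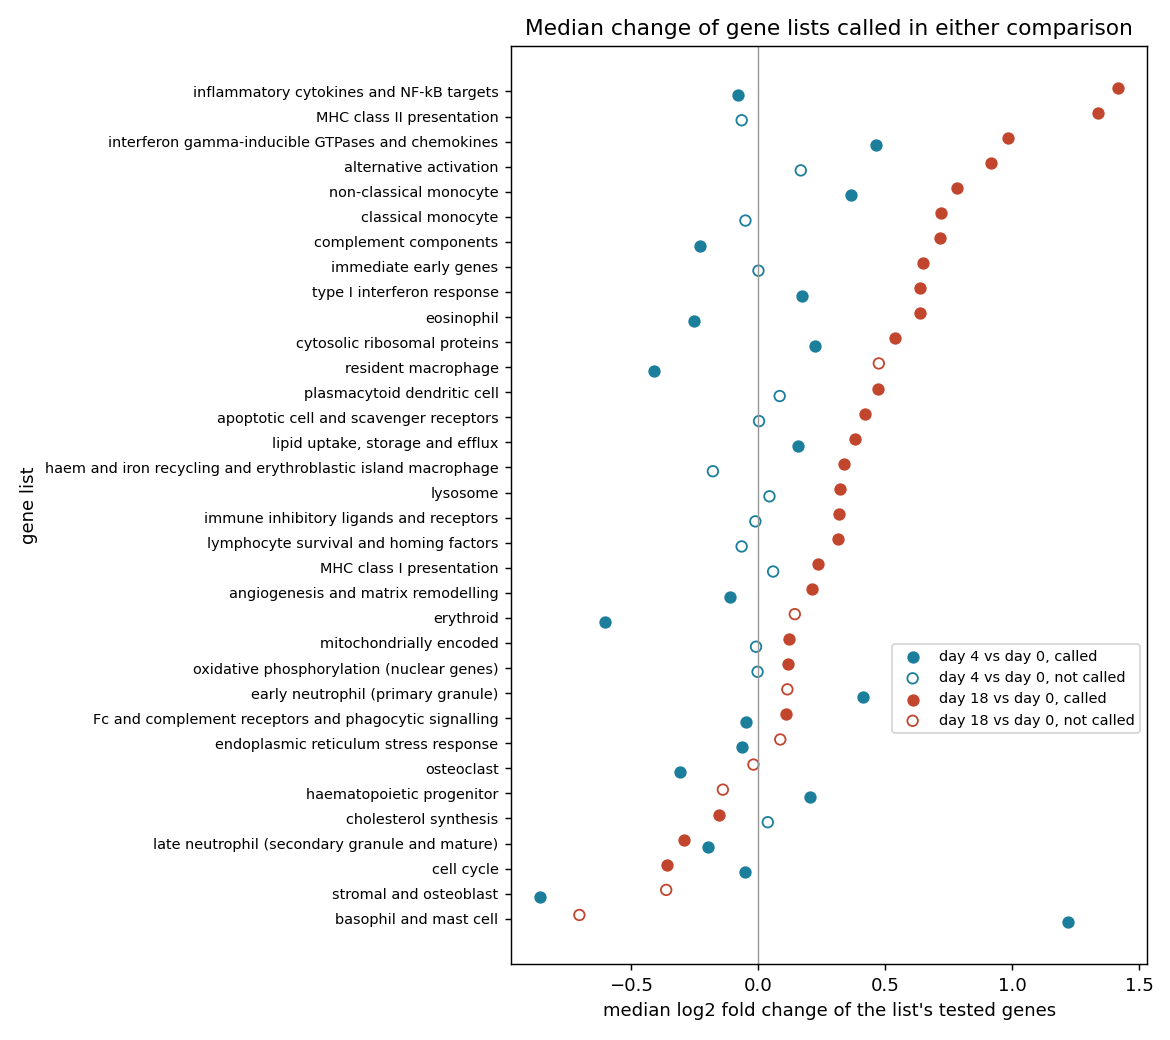
Median log2 fold change of the tested genes (horizontal axis) of each fixed gene list (vertical axis) that camera called in at least 1 of the comparisons of day 4 and day 18 with day 0. Blue points show day 4 and red points day 18, filled where camera called the list with its preset correlation. The inflammatory list had a median of -0.08 at day 4 and 1.42 at day 18.

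The comparison of day 18 with day 4 asks what changed between the early and the late time after engraftment. Inflammatory, MHC class II, lysosomal, monocyte and resident macrophage genes rose between these times, and cell cycle, early neutrophil and basophil genes fell. Of these lists only the basophil one lost its call with an estimated correlation (adjusted p = 0.0741). Tgm2 rose from 4.47 ± 0.567 to 74.6 ± 0.732 (16.4-fold), and Cxcl2 from 22.8 ± 0.476 to 163 ± 2.83 (7.11-fold). Il1b rose 2.98-fold, Cd74 2.48-fold and Cd5l 2.69-fold. Mpo fell from 1987 ± 5.05 to 1403 ± 14.8, and Prss34 from 17.9 ± 0.835 to 3.18 ± 0.867. Among genes with a mean log2 level of at least 3, the largest rises were those of Tgm2 (4.04 ± 0.126, adjusted p = 1.79e-19), Socs3 (3.69 ± 0.0930), Cfb (3.56), Cxcl2 (2.83), Bcl3 (2.65), Msr1 (2.59), Tgfbi (2.498) and Rgs1, a regulator of G protein signalling (2.35). The largest falls among such genes were those of Cd209a (-1.55 ± 0.169), Stag3 (-0.87), the immunoglobulin mu constant gene Ighm (-0.80), the linker histone gene H1f2 (-0.79), Slc39a11 (-0.72), Hpgd (-0.72), Cd180 (-0.71) and Taf9 (-0.71). The reads of Cfb, Tgfbi, H1f2 and Taf9 were not whole numbers.

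With an estimated correlation, 13 lists held their call, and each was also called with the preset value. Of the inflammatory genes 30 of 34 rose and 0 fell (32 and 0 adjusted over the list alone), with the NF-kB inhibitor gene Tnfaip3 at 1.78 ± 0.0507. Of the MHC class II genes 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), with H2-Eb1 at 1.67 ± 0.0395. Of the interferon gamma genes 13 of 21 rose and 0 fell (14 and 0 adjusted over the list alone), with Cxcl10 at 1.51 ± 0.158. Of the lysosomal genes 25 of 46 rose and 1 fell (26 and 1 adjusted over the list alone), with Ctsc at 1.89 ± 0.0510. Of the immediate early genes 20 of 24 rose and 2 fell (20 and 2 adjusted over the list alone), with Fosb at 1.16. In that order, the camera adjusted p were 4.50e-30, 9.49e-15, 4.25e-06, 7.52e-15 and 7.53e-17, and with an estimated correlation adjusted p = 0.0366, 0.0440, 0.0470, 0.0440 and 0.0440. Of the complement genes 7 of 8 rose and 1 fell (7 and 1 adjusted over the list alone), with C1qa at 1.26 ± 0.0759. Of the haem and iron genes 12 of 23 rose and 1 fell (13 and 3 adjusted over the list alone), with Fth1 at 0.89. Of the scavenger receptor genes 12 of 25 rose and 1 fell (13 and 1 adjusted over the list alone), with Cd14 at 1.49 ± 0.0586. Of the angiogenesis and matrix genes 16 of 25 rose and 2 fell (16 and 4 adjusted over the list alone), with Mmp14 at 5.41 ± 0.178. The camera adjusted p of these 4 were 6.46e-08, 5.97e-07, 1.26e-05 and 1.03e-07, and with an estimated correlation adjusted p = 0.0440, 0.0440, 0.0476 and 0.0440.

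The remaining 4 of these 13 lists were cell cycle genes and markers of 3 cell types. Of the cell cycle genes 0 of 51 rose and 41 fell (0 and 43 adjusted over the list alone), with Cdc20, an activator of mitotic exit, at -0.50 ± 0.0365. Of the classical monocyte markers 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), with the C-type lectin gene Clec4e at 2.00 ± 0.0726. Of the resident macrophage markers 13 of 19 rose and 1 fell (14 and 2 adjusted over the list alone), with Cd5l at 1.43 ± 0.105. Of the early neutrophil markers 0 of 12 rose and 11 fell (0 and 11 adjusted over the list alone), with Elane at -0.39 ± 0.0233. In that order, the camera adjusted p were 3.27e-25, 9.45e-10, 1.51e-07 and 1.51e-12, and with an estimated correlation adjusted p = 0.0440, 0.0440, 0.0452 and 0.0440. Other cell type markers moved as well. Of the eosinophil markers 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), with Ear6 at 1.54 ± 0.0711. Of the erythroid markers 7 of 14 rose and 1 fell (7 and 1 adjusted over the list alone), with Hbb-bs at 1.48, whose reads may be shared with its copies. Of the basophil and mast cell markers 0 of 9 rose and 6 fell (1 and 7 adjusted over the list alone), with Mcpt8 at -2.01 ± 0.208. Of the osteoclast markers 4 of 8 rose and 0 fell (4 and 0 adjusted over the list alone), with Acp5, tartrate-resistant acid phosphatase, at 1.93 ± 0.154. Their camera adjusted p were 6.93e-09, 0.00142, 0.000493 and 0.00146, and with an estimated correlation adjusted p = 0.0543, 0.0760, 0.0741 and 0.0760. Of the late neutrophil markers 7 of 20 rose and 8 fell (7 and 11 adjusted over the list alone), with a median of -0.10 and a mean of 0.06, which differ in sign (camera adjusted p = 0.0175, and adjusted p = 0.117 with an estimated correlation).

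Calls that ended with an estimated correlation covered immune, metabolic and technical lists. Of the type I interferon genes 29 of 45 rose and 4 fell (31 and 4 adjusted over the list alone), with Ms4a4c at 1.07 ± 0.0792. Of the MHC class I genes 12 of 18 rose and 0 fell (12 and 0 adjusted over the list alone), with B2m at 0.26. Of the immune inhibitory genes 13 of 21 rose and 3 fell (13 and 3 adjusted over the list alone), with Lgals3 at 0.50. Of the alternative activation genes 12 of 23 rose and 5 fell (13 and 5 adjusted over the list alone), with Alox15 at 1.82 ± 0.0678. Of the Fc and complement receptor genes 14 of 24 rose and 5 fell (15 and 5 adjusted over the list alone), with Itgax at 2.00. In that order, the camera adjusted p were 5.03e-08, 2.87e-06, 5.20e-05, 0.000586 and 0.000147, and with an estimated correlation adjusted p = 0.0552, 0.0760, 0.0760, 0.0698 and 0.117. Of the lipid genes 10 of 26 rose and 1 fell (11 and 1 adjusted over the list alone), with Plin2 at 0.57. Of the cholesterol synthesis genes 0 of 24 rose and 10 fell (0 and 12 adjusted over the list alone). Of the endoplasmic reticulum stress genes 8 of 24 rose and 2 fell (9 and 2 adjusted over the list alone), with Herpud1 at 0.55. Of the heat shock genes 4 of 12 rose and 1 fell (5 and 1 adjusted over the list alone), with Hspa8 at 0.53. Of the ribosomal protein genes 32 of 44 rose and 0 fell (34 and 0 adjusted over the list alone), with Rplp0 at 0.38. Hspa8 and Rplp0 had reads that may be shared. Their camera adjusted p were 0.00400, 0.000371, 0.00863, 0.0303 and 1.04e-14, and with an estimated correlation adjusted p = 0.0760, 0.0698, 0.0922, 0.137 and 0.102. For the lists of oxidative phosphorylation, mitochondrially encoded genes, lymphocyte survival factors, plasmacytoid dendritic cells and progenitors, the risers were 8 of 69, 8 of 15, 7 of 13, 5 of 8 and 0 of 11 and the fallers 0, 1, 1, 0 and 5. Adjusted over the list alone, the risers were 7, 8, 7, 5 and 0 and the fallers 0, 1, 1, 0 and 5. Their camera adjusted p were 0.0109, 0.00274, 0.00229, 0.0105 and 0.0170, and with an estimated correlation adjusted p = 0.393, 0.318, 0.0760, 0.108 and 0.309.

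Of the genes reported whatever the result, Csf1r (0.97 ± 0.0349), Cd68 (0.74), Adgre1 (0.50), Ptprc (0.24), Sirpa (0.29), Cd274 (1.55 ± 0.134) and Arg1 (4.13 ± 0.639) rose from day 4 to day 18. The Fc receptor genes Fcgr1 (1.33), Fcgr2b (0.36), Fcgr3 (0.15) and Fcgr4 (0.44) rose. Itgam (-0.08) and Vegfa (-0.38) fell, and Mrc1 (-0.02 ± 0.0700) and Tnf (0.04 ± 0.0555) did not pass. By limma, 3723 genes changed, 1994 higher and 1729 lower (5001 at an unadjusted p under 0.05), and 590 of them at least 2-fold, 555 higher and 35 lower. Camera called 33 of 42 lists, 27 up and 6 down. With library totals alone, with which the median of all genes was 0.0379 instead of 0.00651, 3577 genes were called, 2239 higher and 1338 lower. Against a 1.5-fold change limma called 363 genes higher and 10 lower. On the RPKM scale the count was 2131 (1341 higher, 790 lower) with a pseudocount of 0.1 and 2179 (1386 higher, 793 lower) with 1. With 1 spread for all levels it was 1352 (989 higher, 363 lower). Calls that ended without 1 library were those of oxidative phosphorylation without day 4 A (adjusted p = 0.262) or day 18 B (0.0704), progenitors without day 4 A (0.108) and mitochondrially encoded genes without day 4 A (0.0727). With whole reads only, progenitor (0.0780) and mitochondrially encoded genes (0.0676) were not called. Nor were erythroid and heat shock genes (0.999 and 0.998): the direction of camera's test turned, while the list medians stayed above 0 (0.0971 against 0.71, and 0.0685 against 0.14). Late neutrophil markers were not called without the 20 most abundant genes (0.111), and their median was then 0.20.

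The changes at day 4 and day 18, both measured against the same day 0 libraries, were set side by side. Of the genes tested, 585 were higher at both times and 678 lower at both, where independent lists of these sizes would share 141.3 and 164.4, and 137 changed in opposite directions, where independent lists would give 307.0. Independent lists leave out the shared day 0 libraries, and no simulated value was made for these counts. Across genes, which are not independent replicates, Pearson's r was 0.393 and Spearman's rho 0.490. Unchanged groups simulated against shared, also simulated, controls gave 0.501 and 0.438. The covariance was 0.0841 against 0.0402 in the simulation, a difference of 0.0439. The share of genes with the same sign was 70.3% against 66.6%. Pearson's r thus lay below its simulated value, and the other 3 measures above. The simulation gave both changes the same variance, while the real changes were larger at day 18, so Pearson's r is not directly comparable. The day 0 libraries could not be divided with 2 in each part, so part of the overlap beyond independent lists may come from the shared controls. By the 3 tests together, Ace and Pou2f2 were among 262 genes higher at day 4 and at day 18 than at day 0, with no called change between these times. Ms4a4a, Cd274, Csf1r and Ccr2 were among 309 genes that rose at each step. Socs3 and Bcl3 were among 1218 genes not called at day 4 and higher at day 18 than at both earlier times. Stag3 and Slc39a11 were among 1052 genes not called at day 4 and lower at day 18 than at both. Mki67 and Ltf were among 288 genes that fell at each step. Cxcl2, Il1b and Tgm2 were among 97 genes lower at day 4 and higher at day 18 than at day 0, with a called rise between, and Prss34 and Mcpt8 were among 40 genes with the reverse course.

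**Figure D3:**
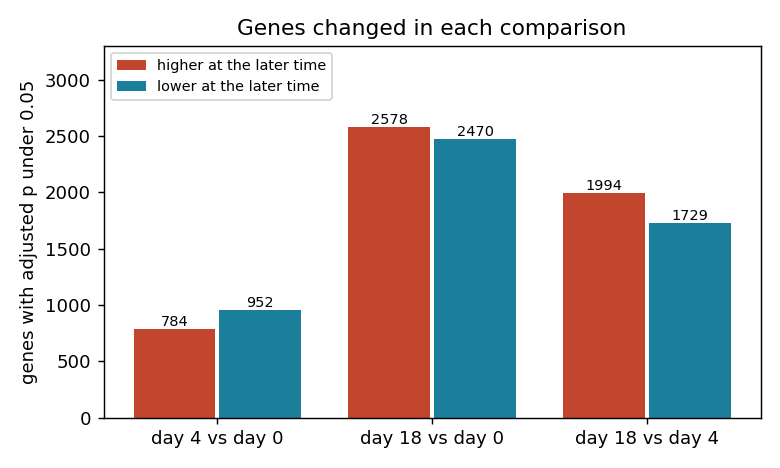
Number of genes that limma called at an adjusted p under 0.05 (vertical axis, from 0) in each comparison (horizontal axis), with genes higher at the later time in red and lower in blue. Day 4 against day 0 had 784 higher and 952 lower genes, and day 18 against day 0 had 2578 and 2470.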

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

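All 8 tests of explanations in the closing section, 7 of them in this part, were chosen after the results were seen, while the test of day 18 against day 4 was planned. The results below were singled out because their called change at day 4 and their called change at day 18, both against day 0, had opposite signs. Limiting the list to opposite signs was also decided after the data were seen. Values in brackets are the log2 differences of day 18 from day 4, with genes called by limma and lists by camera. Results chosen for opposite signs must differ between these days, so this difference is no independent evidence.

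Inflammatory and signalling genes were lower at day 4 and higher at day 18 than at day 0: Cxcl2 (2.83), Ccrl2 (1.75), Il1b (1.58), Tnfaip3 (1.78), Nfkbia (1.095), Clec4e (2.00), Hcar2 (1.97) and Tgm2 (4.04). So were the MHC genes Cd74 (1.31), H2-Eb1 (1.67) and B2m (0.26), the complement genes C1qa (1.26), C1qb (1.09) and Cfp (0.77), and the macrophage and lipid genes Cd5l (1.43), Nr1h3 (2.76), Plin2 (0.57), Fth1 (0.89), Acp5 (1.93) and Mmp14 (5.41). The same course held for the haemoglobin genes Hbb-bs (1.48), Hba-a1 (1.38) and Hba-a2 (1.40), the eosinophil-list genes and lipoxygenase gene Ear1 (1.86), Ear6 (1.54) and Alox15 (1.82), and Ptprc (0.24) and Hspa5 (0.39). Some day 4 falls were small: the log2 change from day 0 was -0.0883 for B2m, -0.0906 for Cd74, -0.112 for Nfkbia and -0.146 for H2-Eb1. Camera called neither MHC list at day 4. In the class II list 2 of 11 rose and 2 fell (camera adjusted p = 0.980). In the class I list 3 of 18 rose and 1 fell (camera adjusted p = 0.187). The reverse course, higher at day 4 and lower at day 18, was that of the basophil proteases Prss34 (-2.48) and Mcpt8 (-2.01), and of Myb (-0.39), Ighm (-0.80), H1f2 (-0.79) and Cdc20 (-0.50). Of the lists, camera called opposite directions for inflammatory genes (median 1.79), complement components (1.21), eosinophil markers (0.70), angiogenesis and matrix genes (0.41) and Fc and complement receptors (0.19). In that order, adjusted p = 0.134, 0.168, 0.168, 0.185 and 0.428 at day 4 with an estimated correlation and 0.0492, 0.0876, 0.111, 0.112 and 0.318 at day 18, so all 5 day 4 calls ended and only the inflammatory one held at day 18. The day 4 call of the Fc list also ended without day 0 A (0.0521), day 0 B (0.125) or day 4 B (0.206), and by fry (0.111). The day 4 fall of Acp5 (-0.51) was not called without day 0 A (adjusted p = 0.116), day 0 B (0.154), day 4 A (0.307, with a log2 change of -0.27), day 18 A (0.0717) or day 18 B (0.0650), with library totals alone (0.0528) or with only the 4 libraries compared (0.09999).

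The rise of inflammatory, MHC class II and monocyte genes at day 18 was weighed against 3 technical explanations. A lower share of neutrophil-lineage cells, as the only change, would raise the markers of all other cell types alike. Of 84 called markers of other types (140 tested) 59 were higher and 25 lower than at day 0. A lower share together with uneven shifts among the other cell types could give both directions, so the test cannot exclude it. Fewer reads taken by the 20 most abundant genes would raise all other genes by only 0.0618 on the log2 scale. More monocytes among the sorted cells, each with unchanged expression, would raise genes specific to them alike. Of the classical monocyte markers 9 rose while 5 fell, which argues against this as the only change, as far as the markers are specific. More monocytes beside other shifts cannot be told apart from a change within cells. The median rise of the inflammatory list exceeded that of the monocyte markers by 0.697 (bootstrap standard error 0.705), which does not decide it. The growth of the lymphoma between the days stays open as well, untested, as do differences in handling, since the labels do not give the days of sorting. Without ungrafted mice at day 18, the injection and the time passed stay open too.

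For the lower erythroid, macrophage and eosinophil-list genes at day 4, less RNA of all cell types outside the neutrophil line would lower their markers together, but of 63 called markers (140 tested) 37 were lower and 26 higher than at day 0. That speaks only against a loss shared alike by all these cell types, and uneven losses are not excluded. Fewer eosinophils would lower Prg2 and Epx, whose sum changed by 0.106 (standard error 0.0683) while that of Ear6 and Alox15 changed by -0.81 (standard error 0.0394). These genes were chosen with their values known. Epx was the only called riser of the eosinophil list, in which 6 of 11 genes fell. The test therefore cannot exclude fewer eosinophils. Reads shared between near-identical genes cannot be behind the macrophage and eosinophil-list falls as a whole, since 15 of 16 called members had whole reads, all but Ear1. Of the erythroid genes, 2 of 6 had whole reads, neither of them a haemoglobin gene. Both alpha haemoglobin copies fell, Hba-a1 from 59.8 ± 7.08 to 35.4 ± 3.36 and Hba-a2 from 70.6 ± 2.62 to 36.9 ± 1.54. These values argue against reads moved between the 2 copies. Sharing with other genes stays open for the erythroid genes. With whole reads only, and so fewer genes, the list median was -0.45 against -0.60, without a call by camera (adjusted p = 0.0673). A change of expression in the sorted cells soon after engraftment is a hypothesis from these data that was not itself tested, and differences in handling between the days stay open, untested.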

How the results depend on the processing

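Alternatives with another pseudocount, RPKM scale, another trend of the spread, whole reads only, without the 20 most abundant genes or with a block were chosen after the result was seen, and the others were planned. Counts of called genes stayed within 1.5 times their main values under limma-voom, median-of-ratios factors, library totals alone, both other filters, no robust moderation, only the 4 libraries compared, other pseudocounts, whole reads only and without the 20 most abundant genes. Against a fold of 1.5, which asks for larger changes, limma called 12 genes at day 4 and 517 at day 18 against day 0, and 373 between day 4 and day 18. The RPKM scale gave 95 genes at day 4 against day 0 (65 higher, 30 lower) with a pseudocount of 0.1 and 52 with 1, against 1736, and 2131 and 2179 for day 18 against day 4, against 3723. With the spread following RPM the RPKM scale gave 748. With 1 spread for all levels, 0 genes were called at day 4 (2454 at an unadjusted p under 0.05), 2646 at day 18 against day 0 and 1352 against day 4. These settings let a gene borrow less from others: prior degrees of freedom were 1.59 on the RPKM scale with 0.1 and 1.22 with 1 spread, against 22.9. In simulated data for day 4 against day 0 they recovered 6.25% and 0% of the smallest simulated changes, against 58.3%, with 7.48%, 9.18% and 6.06% of calls false in that order. The simulation gave all genes the same spread beyond counting noise, so its spread followed the read level as in the main model. It therefore favoured that model and cannot say which setting suits the real data. The number of genes called at day 4 thus rests on the chosen model of the spread. Leaving out 1 library gave 916 to 1548 genes at day 4 against day 0, 3626 to 5390 at day 18 against day 0 and 2541 to 3621 between them, and 16 to 21, 23 to 26 and 30 to 33 lists. The lone library of a group was then assumed to vary like the other groups. The correlation of the changes at day 4 and day 18 was 0.316 to 0.499 with 1 library left out (0.470 without day 0 B), against 0.393, and the cause was not tested. With an estimated correlation camera called 0, 3 and 13 lists, against 20, 26 and 33 with the preset one, and with whole reads only 15, 19 and 29 with the preset one. The estimated setting changes more than the correlation, since camera then also tests each list on the 3 residual degrees of freedom. Calls also ended for lists with an estimate below the preset 0.01, such as early neutrophil markers at day 4 (-0.0708). A call lost with this setting is therefore by itself no sign of correlated members. Named genes that were called numbered 77 at day 4, 95 at day 18 and 116 between. Some of these calls ended when 1 library was left out. Under another scaling, filter, pseudocount, moderation or set of genes, or with only the 4 libraries compared, 6, 1 and 0 lost the call. Over the 3 comparisons, limma-voom ended 2 calls and the block 1. Counting also the test against a fold of 1.5, the RPKM scale and 1 spread for all levels, 77, 38 and 62 lost the call under at least 1 setting. No called gene that was named reversed. Of named genes not called, Fcgr3 at day 4 was 0.0241 with library totals alone, and Mrc1 between day 4 and day 18 was 0.0133 with library totals alone and from -0.0693 (without day 4 B) to 0.0280 (without day 4 A) with 1 library left out. Of lists called between day 4 and day 18, the direction of the test reversed for late neutrophil markers without the 20 most abundant genes (median 0.20) and for erythroid (0.0971) and heat shock genes (0.0685) with whole reads only. Of lists not called, it reversed by fry for classical monocyte markers at day 4 (-0.0504) and for glycolysis at day 18 against day 0 (0.0104) and day 4 (0.0336). For these reversals the cause was not tested. The letters of the columns match no label of the samples, so the planned pairing by replicate number was tried with the letter as a replicate block instead, which gave 1656, 4932 and 3661 genes and 19, 26 and 33 lists. The differences of A from B had correlations near 0 between groups (-0.0179, 0.00180 and -0.0419), so the letters show no pairing. The planned count models were not run on the RPKM values; limma-voom on the recovered reads, some of which are fractions, was the nearest alternative. The median standard error of a log2 fold change, 0.11, reflects depth and the spread between libraries together, and that of single genes differs with their level.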

Other observations

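All families and genes in this part, and its test of an explanation, were chosen after the results were seen. Chemokine genes rose at day 18: against day 0, 18 of 21 rose and 2 fell, with a median log2 fold change of 2.00. In the Ms4a family 8 of 10 rose and 0 fell, among the Toll-like receptors 8 of 12 rose and 1 fell, among the Trem and Cd300 receptors 9 of 14 rose and 2 fell, and among the Clec4 and Clec7 lectins 5 of 10 rose and 1 fell. Camera, adjusted over 6 families, gave adjusted p of 3.69e-08, 3.61e-07, 4.94e-05, 0.000292 and 0.000977 in that order, and adjusted p = 0.0424, 0.0424, 0.0424, 0.0431 and 0.0475 with an estimated correlation. Families picked with their values known make these p-values descriptive only, and they give no independent support. Adjusted over 6 families, they cannot be set beside those of the 42 fixed lists. Chemokine genes are also part of the inflammatory list. Already at day 4, 6 of 10 rose and 0 fell in the Ms4a family (camera adjusted p = 2.67e-08, and adjusted p = 0.0547 with an estimated correlation). Of the core clock genes, 4 of 13 rose and 2 fell at day 18, and camera did not call them (adjusted p = 0.242).

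Several genes with few or no reads before day 18 had many then. Spon1, a secreted matrix protein, had 18 and 14 reads at day 0 and 863 and 1032 at day 18 (5.72, adjusted p = 4.86e-17). Vcan, the proteoglycan versican, had 44 and 29 and then 884 and 1003 (4.65, adjusted p = 5.48e-15), and the protease gene Htra1 3 and 0 and then 107 and 122. The interleukin 6 gene Il6 had 7 and 2 reads at day 0 and 50 and 62 at day 18 (3.23, adjusted p = 2.54e-05). The chemokine gene Ccl8 had 0 reads in all 4 libraries of day 0 and day 4, and 40 and 59 at day 18. Cxcl1 had 27 and 29 reads at day 0, 6 and 6 at day 4, and 81 and 113 at day 18. The macrophage receptor genes Cd163 (-0.58, adjusted p = 0.00774) and Siglec1 (-0.57, adjusted p = 0.000137) fell at day 18 against day 0.

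Neutrophil transcripts were among the most abundant of the sorted cells. Of the 20 late neutrophil markers, 17 lay above the macrophage gene Csf1r (159.5 RPM) at day 0, with a list median of 689.9. Transcripts of these genes were thus in the libraries. Whether they came from neutrophil-lineage cells or from RNA of such cells stays open: this count restates the abundance that was seen and does not decide it. The 20 genes took 14.6 ± 0.00762% of reads at day 0. The primary granule genes Mpo and Elane stood at 1198 ± 3.14 and 494 ± 3.05 RPM, the macrophage genes Adgre1 and Cd68 at 34.6 ± 0.966 and 36.6 ± 2.78. As far as the neutrophil markers are specific, these values argue against the sorted macrophages as their main source. The sort for CD11b and F4/80 thus did not keep these transcripts out of the libraries. Changes in these libraries therefore cannot be assigned to macrophages alone. Ngp alone held 3.40% of all reads, S100a9 3.21% and S100a8 1.98%. Bone marrow holds such cells, and 2 of the 20 genes, Mmp8 and Mmp9, are also in another list. No biological explanation was tested for this pattern.

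The share of reads in early neutrophil markers was 0.350 ± 0.00192% at day 0, 0.510 ± 0.000397% at day 4 and 0.391 ± 0.000485% at day 18 (n = 2). In immediate early genes it was 0.412 ± 0.00210%, 0.443 ± 0.00485% and 0.612 ± 0.00275%, and in the B cell list 0.1004 ± 0.00202%, 0.0962 ± 0.00262% and 0.0887 ± 0.000421%.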
